A study of Danio rerio with 6 samples.

How the data were processed

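RNA was measured in 6 samples of AB wild-type zebrafish embryos at 52 hours post fertilization on an Affymetrix zebrafish expression array. Per the labels, each sample was a pool of 10 dissected tissues. The 3 retina pools were described as retina, and the 3 retina with RPE pools as retina with the retinal pigment epithelium (RPE, the pigmented cell layer behind the photoreceptors) attached. Per the labels' protocols, 33 ng of total RNA per pool went through biotin labelling with 2 cycles of amplification. The labels call the pools biological replicates.

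The deposited values are linear intensities, 1 per probe set and array. The submitters' processing notes name RMA, the affy package and R 2.2.0, with no order of steps. RMA is a method that corrects background, equalizes the arrays and summarizes the probes of each probe set. Whether other arrays entered that normalization is not given in the sources used here. The linear scale was read from the values, whose array medians lay between 68.7 and 74.5. The arrays did not have identical quantiles, so the deposited values were not forced to 1 common distribution over these 6 arrays. The quartiles followed the groups. The lower quartile was 24.9 to 26.0 in retina and 27.8 to 28.4 in retina with RPE, and the upper 285 to 293 and 265 to 271. The arrays with RPE thus had a narrower spread of values.

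In all 15617 probe sets were given. The 115 control probe sets were left out of the tests, which leaves 15502. Gene names came from the platform annotation, updated through gene identifiers where a current gene list held them. Of the tested probe sets, 10795 were listed with 1 gene, 135 with several and 4572 were not listed. The named probe sets covered 8793 genes. A current identifier was matched for 10711 probe sets, and 1 symbol was updated. A gene was represented by its probe set with the highest mean log2 value over the 6 arrays, and other probe sets of named genes are given where they disagree. No detection call or background level is in the values used here, so dim probe sets have no floor and their folds can understate a change.

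Intensities were log2 transformed. Retina with RPE was compared with retina in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, 2-sided, with Benjamini-Hochberg adjustment over the 15502 probe sets. A probe set was called at an adjusted p under 0.05. Errors beside log2 changes are standard errors (SE) of limma, and intensities are means ± SD over 3 pools. The number of arrays limits the precision: an exact permutation test of 3 against 3 arrays cannot give a p under 0.1, so calls rest on the spread that limma pools over probe sets. In data simulated from the retina with RPE against retina comparison, with 15502 probe sets, this fit recovered 88% of changes of log2 1 and 47% of changes of log2 0.5, with 4 false calls. Only 100 probe sets were changed at each size, and the noise was normal and independent between probe sets. No trend with brightness, probe set class or labelling was simulated, so the false calls are not the error rate of the real comparison.

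The design, the alternatives, the naming rule and 22 gene lists were fixed before the data were examined. Named genes were the 10 largest called changes in each direction with separated groups, up to 4 called members of each list, and a short set of RPE and retinal genes given wherever measured. Of that set tyrp1b, pmela and rlbp1b had no probe set of their own among those used here, and 1 further gene is not reported here. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists. Camera with an estimated correlation and fry were alternatives. List medians were also set against 10000 random lists matched on mean level in 20 bins, as a description.

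The study estimated RPE levels by deducting a yield-adjusted retina value from each retina with RPE value. The yields are not used here. The retinal share was instead taken as the median ratio of retina with RPE over retina across genes of the photoreceptor, retinal neuron and synaptic lists with a retina mean log2 value of 8 or more. That takes their expression in RPE as 0. The RPE over retina fold was then the ratio minus the share, divided by 1 minus the share. Its interval carries the 95% limma interval with the share held fixed, and an estimate at or under 0 has no fold. The sign and the test are those of the direct comparison for any share under 1.

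The alternatives fixed in advance were the replicate number as a block, centring on ribosomal protein genes, cyclic loess, a filter on dim probe sets, eBayes with trend and robust, array weights, an ordinary test per probe set, stricter thresholds, a pseudocount of 16, the median over the probe sets of a gene, other sets of genes for the share, fixed shares, and leaving out each array. Quantile normalization over the 6 arrays, and the block together with an estimated correlation, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.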

Results

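Transcript levels were measured on 6 arrays, 3 of retina and 3 of retina with the retinal pigment epithelium attached, from wild-type zebrafish at 52 hours post fertilization. Array medians were 69.1, 68.7 and 69.6 in retina and 73.2, 73.2 and 74.5 in retina with RPE. Replicate arrays correlated across probe sets at r = 0.994 to 0.995 in retina and 0.996 to 0.997 in retina with RPE, against 0.980 to 0.988 between the groups. Probe sets are not independent replicates, so these correlations describe the arrays only. The first principal component held 69.6% of the variance and separated the groups. The log2 ratio of the 3' over the 5' probe set of gapdh, a measure of RNA length after labelling, was 3.12 ± 0.149 in retina and 2.99 ± 0.212 in retina with RPE (SD, n = 3, exact permutation p = 0.5). Bacterial poly-A control probe sets, left out of the comparison, read 1.97-fold to 3.47-fold higher in retina with RPE (exact permutation p = 0.1, the smallest possible).

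The comparison of retina with RPE against retina asked which transcripts the epithelium adds to the dissected tissue. The largest rise was that of rpe65a, the retinoid isomerase of the visual cycle, from 73.8 ± 12.1 to 906.6 ± 200.3 (SD, n = 3), a 12.2-fold change with a 95% interval of 9.54 to 15.6 (adjusted p = 2.8e-06, limma). The melanin gene dct, which encodes dopachrome tautomerase, rose 6.33-fold (5.21 to 7.69), from 189 ± 14.2 to 1206 ± 197. The melanosome matrix gene pmelb rose 7.32-fold. Among the 10 genes that fell most, fosab, an immediate early transcription factor, was 3.75-fold lower by its brightest probe set. The gene atoh7, which retinal ganglion cells need to form, was 2.26-fold lower, from 749.5 ± 125 to 329 ± 7.82.

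Of 15502 probe sets, 5355 were called, 2938 higher and 2417 lower with RPE attached. With 1 probe set per gene, 3202 of 8793 genes were called, 1706 higher and 1496 lower. These counts rest on single probe sets. In 204 genes with 2 called probe sets, the first changed by under 2-fold, both lay in the same direction in 58.8%. At least 2-fold change was reached by 62 genes that rose and 64 that fell. The share of called probe sets that lay higher was 54.9%, and 67.5% after centring the arrays on ribosomal protein genes. That centring moved the median of all probe sets from 0.04 to 0.12 on the log2 scale. The share was 48.3% under cyclic loess and 49.9% under quantile normalization, and the filter on dim probe sets gave 1068 higher of 2951 calls. Which direction prevailed therefore depended on the processing. Without retina with RPE replicate 3 the count of called probe sets was 3439, and 1088 genes lay higher. Centring on ribosomal protein genes left 872 genes lower. The groups did not overlap in 49.5% of probe sets, where chance gives 10%.

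Other genes that rose most were gch2 and slc2a15b, both used in yellow pigment cells, crestin, a marker of neural crest, the retinol receptor stra6 and the opsin relative rgrb. Their log2 changes were 2.89 ± 0.222 for gch2, 2.16 ± 0.0918 for slc2a15b, 2.24 ± 0.0859 for crestin, 2.12 ± 0.149 for stra6 and 2.04 ± 0.124 for rgrb (SE). A dimmer probe set of gch2 changed by 0.10 and was not called. The genes wu:fc46h12 and defbl1 rose by 3.22 ± 0.274 and 2.87 ± 0.223. Both rpe65a probe sets rose, by 3.61 and 1.56.

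The other genes that fell most were led by supt3h at a log2 change of -1.67 ± 0.183, arhgap46a at -1.47 ± 0.0832, the receptor phosphatase ptprk at -1.38 ± 0.133 and the small Maf gene maff at -1.37 ± 0.113. The fatty acid import gene cpt1ab changed by -1.35 ± 0.151, the junction gene jupa by -1.33 ± 0.121, efhd1 by -1.30 ± 0.134, the cell cycle factor e2f3 by -1.28 ± 0.101 and the paraspeckle gene pspc1 by -1.26 ± 0.0981 (SE). The second probe set of ptprk changed by 0.29 and was not called. Of the other fosab probe sets, 1 fell by 0.97 and the remaining pair rose by 0.39 and 0.36, so the direction of fosab depends on the probe set. The probe sets given for fosab, supt3h, arhgap46a, ptprk, efhd1, e2f3 and pspc1 are marked A in their identifiers. Those of maff, cpt1ab and jupa are marked S. In 65.6% of 943 genes with both classes the A probe sets lay lower than the S ones. Whether the falls above follow the class was not tested.

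**Figure D1:**
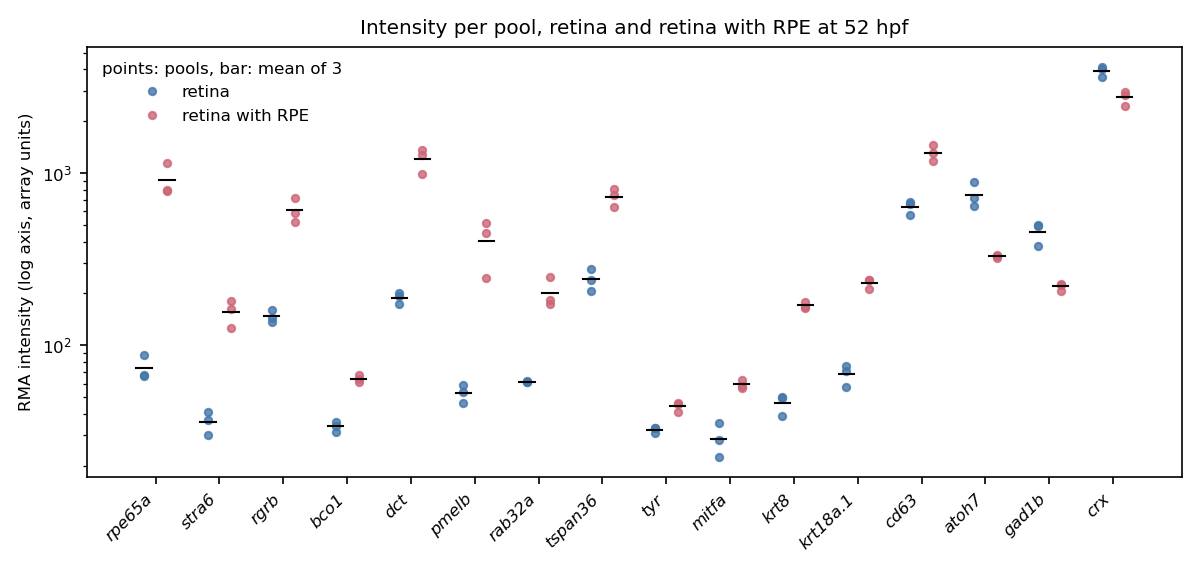
RMA intensity on a log axis for 16 genes, with a point for each pool and a bar at the mean of 3 pools, in retina and in retina with RPE. The 3 retina with RPE pools lie above the 3 retina pools for rpe65a, dct, tyr and mitfa, and below them for atoh7, gad1b and crx.

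All 6 measured genes of melanin synthesis and melanosomes rose (6 adjusted over the list alone). Besides dct and pmelb, the melanosome trafficking gene rab32a rose 3.24-fold and tspan36 3.02-fold. The tyrosinase gene tyr rose from 32.4 ± 1.37 to 44.4 ± 3.03, 1.37-fold. The list lay higher by camera (adjusted p = 7.8e-14). Camera with an estimated correlation gave adjusted p = 0.242, and the alternatives without that correlation 1.6e-28 to 0.00113. In the same pools genes of neural crest and other pigment cells, some of which also make melanin, had a median log2 change of 0.53, and genes of mesenchyme and cartilage 0.50.

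Of 18 genes of retinoid handling and the visual cycle, 5 rose and none fell (5 and 0 adjusted over the list alone). They were rpe65a, stra6, rgrb, bco1, which cleaves carotenoids, at 1.90-fold, and the retinoic acid hydroxylase gene cyp26a1 at a log2 change of 0.67. The list lay higher by camera (adjusted p = 1.0e-05). Camera with an estimated correlation gave adjusted p = 0.292, and the alternatives without that correlation 4.8e-08 to 0.00166. Its median of 0.18 stood at percentile 95.46 of random lists of the same level, inside their central 95% (-0.13 to 0.21). Of 15 genes of RPE membranes, junctions and phagocytosis, 6 rose and 0 fell (6 and 1 adjusted over the list alone). Simple epithelial keratin genes led it, with krt8 at 3.72-fold, krt18a.1 at 3.40-fold and krt18b at 2.67-fold, ahead of cd63, which encodes a tetraspanin of lysosomes and melanosomes, at 2.06-fold. The list lay higher by camera (adjusted p = 1.1e-04). Camera with an estimated correlation gave adjusted p = 0.254, and the alternatives without that correlation 2.4e-06 to 9.7e-04. Its median of 0.15 stood at percentile 89.48 of random lists of the same level, inside their central 95% (-0.17 to 0.22). In the same pools 11 of 37 genes of skin and cornea also rose, with ahnak at a log2 change of 1.63 and the keratin gene krt94 at 1.03, as did 21 of 31 genes of mesenchyme and cartilage.

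The 9 RPE transcription factors did not move together. Of these, 3 rose and 4 fell (4 and 4 adjusted over the list alone), with camera adjusted p = 0.867 and a median and a test of opposite sign. The melanocyte and RPE factor mitfa rose 2.11-fold, from 28.7 ± 6.59 to 59.4 ± 3.21, and sox9a 1.53-fold. The gene otx2a, dim at 43.0 in retina, rose by a log2 change of 0.48. In contrast otx2b was 1.48-fold lower and the bright probe set of yap1 was 1.53-fold lower, while its second probe set, at 0.07, was not called.

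Of 37 genes of retinal ganglion, amacrine, horizontal and bipolar neurons, 14 fell and 3 rose (14 and 3 adjusted over the list alone). The list lay lower by camera (adjusted p = 0.0178), with adjusted p = 0.232 with an estimated correlation. Its median of -0.14 stood at percentile 6.64 of random lists of the same level, inside their central 95% (-0.17 to 0.08). Besides atoh7, the GABA synthesis gene gad1b was 2.06-fold lower, the chemokine receptor gene cxcr4b 1.95-fold and the amacrine factor tfap2b 1.66-fold. After cyclic loess, quantile normalization or the filter on dim probe sets the call of the list was lost, within a range of 0.00419 to 0.144 over the alternatives other than an estimated correlation. Of 10 synaptic vesicle genes 6 fell and 0 rose (7 and 1 adjusted over the list alone), with camera adjusted p = 0.00435 and adjusted p = 0.361 with an estimated correlation. The filter on dim probe sets also ended that call (0.0881, in a range of 1.5e-04 to 0.0881 over the alternatives other than an estimated correlation). They included the synapsin gene syn1 at a log2 change of -0.69 ± 0.140 and the synaptophysin gene sypb at -0.66 ± 0.174, which lost its call without retina with RPE replicate 2 (adjusted p = 0.0716) or 3 (0.0713). The brighter probe sets of nsfa and sncb changed by -0.98 and -0.72, and the others by 0.25, not called, and 0.41, called. The brighter ones, and those given for syn1 and sypb, are marked A in their identifiers, and the dimmer ones of nsfa and sncb are marked S. A probe set of sypb marked S changed by -0.47 and was called. Among random lists of the same level, where bright probe sets lay lower as a whole, the median of the synaptic list stood at percentile 0.02.

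Photoreceptor genes moved both ways. Of 36, 8 rose and 5 fell (8 and 5 adjusted over the list alone), with camera adjusted p = 0.295. The photoreceptor factor crx was 1.43-fold lower, from 3931 ± 282 to 2747 ± 257, while the dim cone genes pde6c and opn1mw2 rose 1.84-fold and 1.79-fold. Probe sets of 2 genes opposed each other, at -0.95 and 0.93 for pde6ha and at -0.88 and 0.43 for rcvrn2. Of 46 genes of retinal progenitors and patterning, 9 rose and 13 fell (11 and 14 adjusted over the list alone), with camera adjusted p = 0.905 and a median and a test of opposite sign. The Notch target gene her4.2 was 1.67-fold lower and so was the neural stem cell factor gene sox2, although the other sox2 probe sets, at -0.08 and 0.14, were not called. In the same list notch1b rose 1.70-fold and the Wnt antagonist gene sfrp1a 1.77-fold.

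Of 53 genes of the cell cycle and DNA replication, 10 rose and 12 fell (10 and 12 adjusted over the list alone; camera adjusted p = 0.261). The origin recognition gene orc6 was 2.29-fold lower and e2f7 was 1.79-fold lower, whereas the spindle checkpoint kinase gene ttk rose 1.64-fold. The bright probe set of zgc:110540 changed by -1.10 and its second, at 0.14, was not called. Of 32 genes of lysosomes and the vacuolar ATPase, 3 rose and 12 fell (3 and 12 adjusted over the list alone). The pump genes atp6ap2 and atp6v1b2 were 1.99-fold and 1.63-fold lower, the cholesterol transporter gene npc1 1.68-fold and the protease gene lgmn 1.57-fold. The list was called by camera (adjusted p = 0.0202). Camera with an estimated correlation gave adjusted p = 0.434, and the alternatives without that correlation 0.00423 to 0.145. Its median of -0.17 stood at percentile 3 of random lists of the same level, inside their central 95% (-0.17 to 0.10). It lost its call without retina replicate 1 (adjusted p = 0.0838), among other settings. The gene atp6v1b2 lost its own without that array (0.0535) and without retina with RPE replicate 2 (0.0588) or 3 (0.0829).

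The remaining general lists were not called. Ribosomal protein genes had 2 of 70 higher and 4 lower (1 and 3 adjusted over the list alone; adjusted p = 0.261), oxidative phosphorylation 11 of 85 higher and 10 lower (10 and 10 adjusted over the list alone; adjusted p = 0.580), and the proteasome 1 of 42 higher and 5 lower (1 and 3 adjusted over the list alone; adjusted p = 0.435). The test of each of these lists changed direction under cyclic loess. Immediate early and heat shock genes, whose levels can follow dissection, had 15 of 41 higher and 8 lower (16 and 9 adjusted over the list alone; adjusted p = 0.644). Here hsp70.3 rose 2.32-fold, dusp2 was 1.92-fold lower, and the bright probe set of gadd45ba was 1.74-fold lower while its second was not called at 0.21.

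Of the lists of other cell types, those of mesenchyme, neural crest and muscle stood highest in the retina with RPE pools against random lists of the same level, at percentiles 100, 100 and 98.95. The medians of leukocyte (93.75), erythrocyte (93.46), endothelial (79.47), lens (78.06) and skin genes lay inside the central 95% of such lists. Of 31 genes of mesenchyme, cartilage and extracellular matrix, 21 rose and 0 fell (23 and 0 adjusted over the list alone). The cartilage collagen genes col2a1a and col9a2 rose 3.53-fold and 2.51-fold, the matrix gene sparc 2.34-fold and snai1a 2.23-fold. The median log2 change was 0.50 (camera adjusted p = 9.3e-08). Camera with an estimated correlation gave adjusted p = 0.232, and the alternatives without that correlation 2.0e-13 to 0.00342. Of 12 genes of neural crest and other pigment cells, 7 rose and 0 fell (8 and 0 adjusted over the list alone), led by gch2, crestin and slc2a15b, with scarb1 at 1.88-fold. Camera gave adjusted p = 8.3e-14, and 0.232 with an estimated correlation. The alternatives without that correlation gave 1.1e-14 to 9.7e-04.

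Of 34 skeletal muscle genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone), with eno3 at 2.59-fold and the actin gene acta1a at 1.78-fold. Camera gave adjusted p = 1.5e-04, with adjusted p = 0.232 with an estimated correlation. Of 22 leukocyte genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone), including coro1a at a log2 change of 1.07 ± 0.111 (SE), lcp1 at 0.76 ± 0.103 and the brightest mpx probe set at 1.01 ± 0.0885, while 2 other mpx probe sets were not called. The leukocyte list had adjusted p = 0.00146, with adjusted p = 0.232 with an estimated correlation. The leukocyte gene arhgdig rose 1.49-fold by 1 probe set, and the other was not called. Of 37 genes of skin and cornea, 11 rose and 2 fell (11 and 2 adjusted over the list alone), including ahnak (log2 change 1.63 ± 0.135, SE) and krt94 (1.03 ± 0.0948). That list had adjusted p = 0.0186, with adjusted p = 0.361 with an estimated correlation, and lost the call under cyclic loess and quantile normalization. Its median of 0.12 did not exceed that of random lists of the same level (percentile 46.51).

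Vessel endothelium had 6 of 12 genes higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.0397), with adjusted p = 0.331 with an estimated correlation. The endothelial genes plvapb and flt4 rose 1.88-fold and 1.71-fold. The brightest probe set of cldn5a changed by -1.12, another rose by 0.35 and a further one was not called. Erythrocyte genes had 7 of 20 higher and 1 lower (9 and 3 adjusted over the list alone; adjusted p = 0.0397), with adjusted p = 0.361 with an estimated correlation. The globin gene hbbe2 rose 1.64-fold. Each of these 2 lists lost its call in 7 of the alternatives other than an estimated correlation. Endothelium did so without retina replicate 2 (0.0595) or 3 (0.0698), and erythrocytes without retina replicate 1 (0.0838) or 3 (0.0551) or retina with RPE replicate 1 (0.0513). Lens genes had 4 of 15 higher and 0 lower (3 and 0 adjusted over the list alone) and were not called (adjusted p = 0.0713), with cryaa rising 1.32-fold, but were called without retina with RPE replicate 1 (0.0324). In all, 13 of the 22 lists were called by camera with the preset correlation, 10 higher and 3 lower. With an estimated correlation 0 were, where 4 had an unadjusted p under 0.05, and fry called 14.

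**Figure D2:**
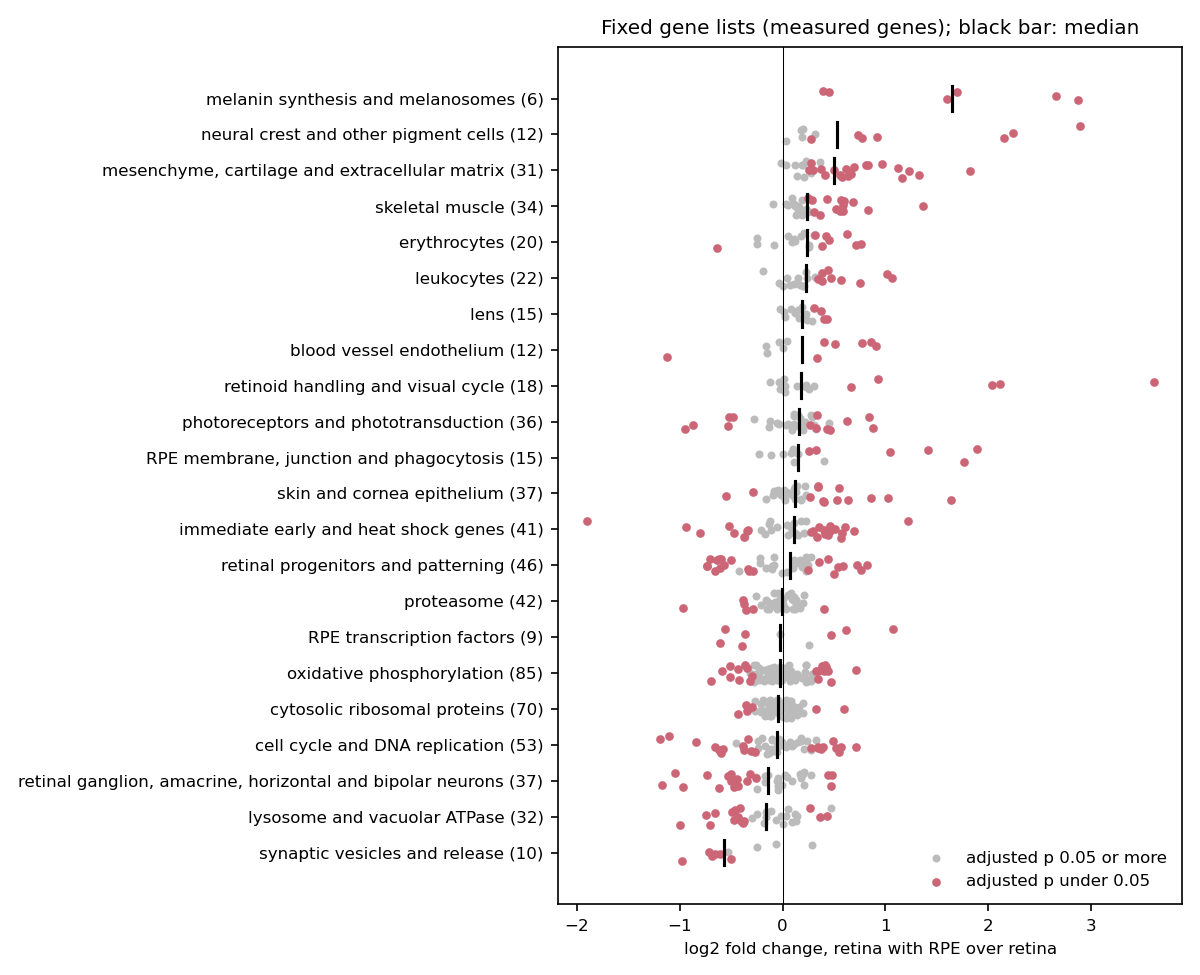
Log2 fold change of retina with RPE over retina for each measured gene of the 22 gene lists, coloured by whether its adjusted p was under 0.05, with a black bar at the list median and the number of genes in parentheses. The highest medians are those of melanin genes at 1.65 and of neural crest genes at 0.53, and the lowest is that of synaptic genes at -0.57.

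To estimate levels outside the retina, as the study did for the epithelium, the retinal contribution was deducted. Over 40 genes of retinal neurons and photoreceptors the median ratio of retina with RPE over retina was 82.0%, with an interquartile range over genes of 68.3% to 97.8%. The 3 pools gave 84.5%, 80.3% and 78.6% (SD 3.03, n = 3). At this share the estimated RPE over retina fold was 63.2 for rpe65a (48.4 to 82.2), 36.1 for pmelb (23.8 to 53.6), 30.6 for dct (24.4 to 38.2), 7.15 for mitfa (4.76 to 10.2) and 3.04 for tyr (2.07 to 4.16). The deduction assigns all tissue other than retina to the epithelium, and markers of other cell types came out higher than in retina too, with 21.6 for crestin, 20.2 for slc2a15b, 15.0 for col2a1a, 9.81 for eno3 and 6.66 for mpx. Whether the retina pools were free of pigment cells was not tested, and dct read 189 ± 14.2 there, above the array medians.

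The estimates moved with the share: rpe65a came to 23.4 at a share of 0.5 and 113 at 0.9, and dct to 11.7 and 54.3. At the estimated share 1700 of the called genes had a fold of 2 or more and 1496 lay at 0.5 or less, of which 1421 were at or under 0 and have no fold. These counts largely restate the calls, 1706 higher and 1496 lower, since a ratio of 1.18 already gives a fold of 2 and a ratio of 0.910 a fold of 0.5. At a share of 0.5 these counts were 342, 1010 and 64. Expression in RPE cannot be negative, yet 1636 of all genes lay at or under 0 at the estimated share. Among them were atoh7 at -2.10 (-2.50 to -1.61) and crx at -0.678 (-1.24 to -0.0271). Both are bright enough to be among the retinal genes whose median ratio set that share. Genes of that set under the median come out negative by construction, so these 2 test neither the share nor simple dilution of retina. Their intervals show only that their ratios lay under the share by more than the limma error. The folds given for rpe65a and the other genes rest on the same share, whose error their intervals leave out. They also rest on 1 probe set per gene. The dimmer rpe65a probe set rose by a log2 of 1.56 against 3.61, and would give a lower fold at any of these shares. Ratios depended on brightness across the whole array, with a median log2 change of -0.13 over probe sets at log2 9 or more and 0.10 over those under 5. Without a minimum level the share came to 0.973, and without retina with RPE replicate 3 the count of genes at 2 or more was 1088.

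**Figure D3:**
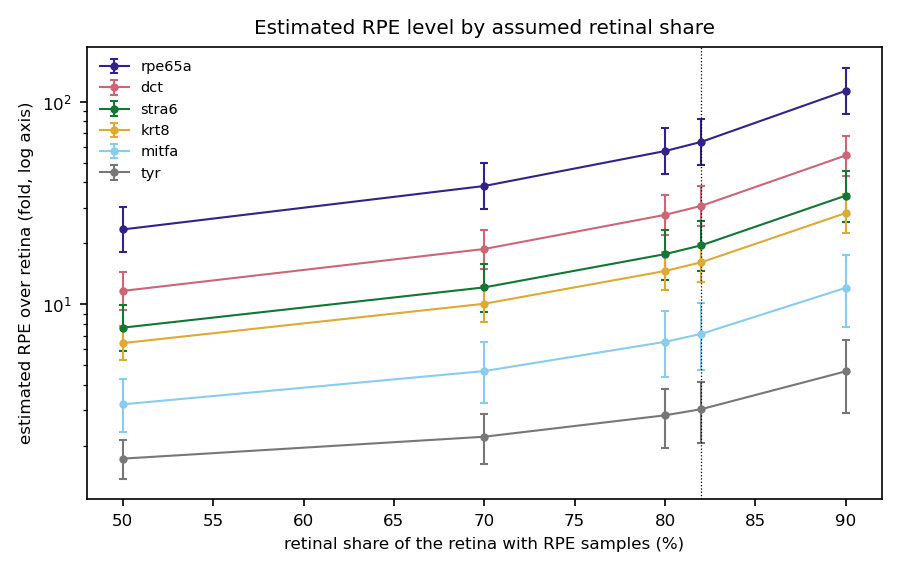
Estimated RPE over retina fold, on a log axis, against the assumed retinal share in percent for 6 genes, with bars for the 95% interval at a fixed share and a dotted line at 82.0%. The estimate for rpe65a, by its brighter probe set, runs from 23.4 to 113 and that for tyr from 1.74 to 4.68.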

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

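Tests of the poly-A controls, of the 2 classes of probe set, of the abundant mesenchyme genes, with both ways of choosing them, and of the other immediate early genes and fosab probe sets were chosen only after the result was seen, as were the repeated draws of probe sets.

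Bacterial poly-A control transcripts, which the comparisons did not use, gave more signal in the retina with RPE arrays. The log2 difference was 1.80 for dap, 0.98 for lys, 1.13 for phe and 1.08 for thr (exact permutation p = 0.1 each, the smallest that 3 against 3 arrays allow). Folds ran from 1.97 to 3.47. The hybridization controls, added after labelling, overlapped between the groups (exact permutation p = 0.3 to 1). Retina replicate 1 read highest of all arrays for each of these, with CreX at 11431 against 6180 to 7246 in the others. That array also read lowest for each poly-A control.

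Most of the called probe sets, 96.2%, changed by less than 2-fold. By limma the real split alone, of 10 splits of the arrays, had as many as 5355 calls, and the highest other had 0. At an unadjusted p under 0.05 the others had 130 to 383, against 7083. Every other split mixes the groups, so a group difference widens its spread and few calls there were likely in advance. With only 10 splits a share under 0.05 is also out of reach, so this test decides nothing. Second probe sets were compared in 542 genes whose first probe set, drawn at random, was called with under 2-fold change. The second lay in the same direction in 55.5% (exact 95% interval 51.2 to 59.8, and 53.0 to 59.4 over 100 repeated draws). Where the second was called too, in 204 of these genes, it did so in 58.8%. Probe sets marked A in their identifiers lay lower than those marked S within the same gene, by a median log2 of -0.14, in 65.6% of 943 genes (62.5 to 68.7). Many of these calls may therefore belong to probe sets rather than to genes. After cyclic loess 69.8% of calls stayed in the same direction, between the bounds set in advance for a trend with brightness, which therefore stays open. A median poly-A difference of 1.11 leaves labelling open too, since both labelling runs that differed and a lower share of mRNA in the RNA could give it, and small differences that the epithelium itself brings were not tested apart from these.

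Genes of mesenchyme and cartilage, and of neural crest, lay higher with RPE attached by camera with the preset correlation, with adjusted p = 0.232 for each list with an estimated correlation. Their list medians lay at percentile 100 of 10000 random lists matched on level, for mesenchyme as for neural crest genes, and muscle genes at 98.95, which argues against a rise of all dim probe sets, whereas leukocyte genes at 93.75, erythrocyte genes at 93.46, endothelial genes at 79.47 and skin genes at 46.51 lay within what such a rise gives. Cells from around the eye in those pools stay open: the more abundant mesenchyme genes, among them sparc at 371 ± 78.5 and col9a2 at 255 ± 53.7 in retina with RPE, had a median log2 change of 0.64 when chosen by level over all arrays, which the change itself can raise, and of 0.49 when chosen by retina level, under the bound of 0.5. Of the 31 mesenchyme genes 4 had a retina mean at or above the array median and 1, sox9a, is also among the RPE transcription factors. Expression of these genes in the epithelium itself stays open as the biological alternative and was not tested. The random lists were matched on level but not on the A and S classes of probe set. Those given for col2a1a, col9a2, sparc and snai1a are marked S, and whether the rises follow the class was not tested.

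The gene fosab lay lower with RPE attached by its brightest probe set. A response shared by most immediate early genes in the retina pools is argued against by the 28 others, with a median log2 change of 0.083 (-0.12 to 0.23), 9 higher and 7 lower, but a response of part of them, such as dusp2 at -0.94 and dusp1 at -0.52, stays open. A single pool is argued against by the smallest change with 1 array left out, -1.68. Another fosab probe set rose by 0.39, so behaviour of single probe sets remains a candidate explanation. A biological difference between the tissues stays open.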

How the results depend on the processing

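Quantile normalization over the 6 arrays and the block with an estimated correlation were the tests chosen only after the data were seen. Under the 12 alternatives computed for each named gene (the scalings, the block, the weights, trend with robust and each array left out), none of 101 changed direction and 10 lost the call in at least 1. Most of these genes were named for large called changes in the same data, so a kept direction was likely in advance. The alternatives also leave out other probe sets of a gene. Those of fosab, pde6ha, rcvrn2, sncb and cldn5a include 1 or more called in the opposite direction. Leaving out each array gave 3439 to 5104 called probe sets (1805 to 2725 higher, 1634 to 2379 lower), 1088 to 1594 genes higher, 1015 to 1487 lower, 11 to 13 lists, a retinal share of 0.784 to 0.829, and 1088 to 1594 genes at an RPE fold of 2 or more. The lowest count, 3439, was without retina with RPE replicate 3, and without replicate 2 of that group 1948 lay higher. Ribosomal centring left 1411 probe sets and 872 genes lower. The filter on dim probe sets, with fewer tested, gave 2951 calls, 1068 higher. A Student test per probe set gave 2331 (1266 higher, 1065 lower), a 2-fold minimum 204 (92 and 112), and adjusted p under 0.01 2666 (1338 and 1328). Called lists numbered 8 under cyclic loess, 8 under quantile normalization, 7 under the filter, 0 with an estimated correlation and 0 with the block and an estimated correlation.

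Same-numbered pools correlated at 0.175, 0.0786 and 0.130 in their deviations, not all over 0.1, so the numbers were not taken to pair them, although each correlated best with its own number, a hint from the data only. The titles of the retina with RPE pools carry another numbering in parentheses, 1, 3 and 4, so the replicate numbers themselves are in doubt. Pools of unequal number correlated at -0.152 to 0.0290. The deviations are from each group mean, so positive values for equal numbers push those for unequal numbers down. The latter are therefore no separate evidence of pairing. The replicate block gave 5786 calls, and among lists moved vessel endothelium to adjusted p = 0.0593 and changed no other list call.

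Adjusted p of lists that lost the call were as follows. With an estimated correlation they were 0.242 for melanin, 0.292 for retinoid, 0.254 for RPE membrane and 0.434 for lysosome genes, 0.331 for endothelium, 0.361 for synaptic, erythrocyte and skin genes, and 0.232 for retinal neuron, leukocyte, mesenchyme, muscle and neural crest genes. With the block and an estimated correlation they were 0.548 for lysosome, 0.445 for erythrocyte and 0.390 for the other called lists. Under cyclic loess they were 0.144 for retinal neurons, 0.145 for lysosome, 0.312 for erythrocytes, 0.253 for endothelium and 0.348 for skin, and under quantile normalization 0.113, 0.123, 0.359, 0.255 and 0.430 in that order. Ribosomal centring gave 0.0581 for erythrocytes and 0.0876 for endothelium, and trend with robust 0.0615 for endothelium. The filter gave 0.0790 for retinal neurons, 0.0881 for synaptic, 0.134 for lysosome and 0.315 for erythrocyte genes, and left too few lens, endothelial and skin genes for a test. By fry, lysosome genes lost the call (0.0648), and photoreceptor (0.0328) and lens genes (0.0312) gained it. With an array left out the range was 0.00423 to 0.0838 for lysosome genes, highest without retina replicate 1, 0.0324 to 0.136 for lens, 0.0288 to 0.0838 for erythrocytes and 0.0413 to 0.0698 for endothelium.

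List tests that changed direction were not called on either side. Under cyclic loess these were progenitors (adjusted p = 0.503), cell cycle (0.535), ribosomal (0.348), oxidative phosphorylation (0.205) and proteasome (0.535), and under quantile normalization the same lists (0.557, 0.557, 0.577, 0.197, 0.577). With the filter they were RPE transcription factors (0.284), oxidative phosphorylation (0.612) and photoreceptor, progenitor, cell cycle, ribosomal and proteasome genes (0.860 each). Progenitors also turned under fry (0.343) and the median over probe sets (0.969). RPE transcription factors turned with an estimated correlation (0.956) and without retina with RPE replicate 2 (0.936, in a range of 0.617 to 0.952 with an array left out). Oxidative phosphorylation turned without retina replicate 3 (0.551, in a range of 0.122 to 0.655).

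The retinal share was 0.693 from synaptic genes alone, 0.973 with no minimum level, 0.879 with ribosomal centring, 0.914 with cyclic loess and 0.889 with quantile normalization. Genes at an RPE fold of 2 or more numbered 342 at a share of 0.5 and 1083 at 0.7. Apart from fewer arrays, fewer probe sets or stricter thresholds, the cause was not tested. Signal over background is unknown here, which limits what dim probe sets can show.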

Other observations

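The split of calls by probe set class and by level, the agreement of second probe sets by size of change, and the stricter reading of the purine test, were tests chosen only after the result was seen.

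The gene atic, which encodes the enzyme of the last steps of de novo IMP synthesis and was singled out after its values were seen, rose 2.56-fold with RPE attached, from 371 ± 76.0 to 939 ± 43.6 (SD, n = 3). Other genes of that pathway and its one-carbon supply also rose: gart by 1.09 ± 0.0868 on the log2 scale, paics by 0.81 ± 0.116, mthfd1b by 0.62 ± 0.108, adsl by 0.61 ± 0.108, shmt2 by 0.59 ± 0.120 and mthfd2 by 0.55 ± 0.165 (SE). In a wider list of 15 purine synthesis genes without atic, 6 rose and 2 fell, guk1b at -0.57 and prps1b at -0.43, with a median of 0.12. That list also holds genes that act before or after IMP synthesis, among them the 2 that fell. Genes of IMP synthesis and its one-carbon supply were not tested apart. As a hypothesis, tissue with RPE may express more of the purine synthesis genes. The wider list passed camera with the preset correlation (p = 0.0475), the bound written before the test. It did not pass camera with an estimated correlation (p = 0.160), and its median had an interval of -0.31 to 0.61. The result is read here as undecided, a stricter reading chosen after that p was seen.

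Probe sets without a gene name here changed too. Of those with the largest changes, 1 rose 4.03-fold with RPE attached, from 23.5 ± 0.715 to 94.9 ± 5.16, and 1 was 3.74-fold lower, from 1354 ± 38.1 to 363 ± 33.1 (SD, n = 3). In all, 1516 of 4707 such probe sets were called, 776 higher and 740 lower.

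Calls differed by class and level of the probe set. Among 8869 probe sets marked A, 16.1% were called higher and 18.6% lower, and among 6633 marked S, 22.8% and 11.6%. By level, 28.3% of probe sets at log2 5 to 7 were called higher and 11.4% lower, against 8.19% and 27.9% at log2 9 or more. Within 145 genes whose A and S probe sets both lay at log2 7 or more, the median difference was -0.25, with the A probe set lower in 69.7%. In a separate random draw of 2 probe sets per gene, the second lay in the direction of the first in 64.7% of 17 genes (exact 95% interval 38.3 to 85.8) where the first was called at 2-fold or more, in 54.6% of 205 at 1.4-fold to 2-fold, in 58.9% of 316 under 1.4-fold and in 53.3% of 1001 where it was not called. Differences between these classes were not tested. What the letters stand for is not given in the sources used here.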
